A study of Mus musculus with 4 samples.

How the data were processed

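Expression was measured in primary hepatocytes isolated from 2-month-old male mice that were wild type (WT) or lacked Chrebp (KO, the gene Mlxipl). Cells were kept for 16 h in medium without serum, with 25 mM fructose or without it (control). The 4 groups of this design were measured on 1 array each, so 4 arrays were analysed. Per the labels, 400 ng of total RNA per sample was amplified, labelled with biotin and hybridised to a 1-colour whole-transcript array.

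The deposited values are log2 expression per probe set, made by the authors before deposit. Per the submitters' processing notes, robust multi-array average (RMA) and R 3.4.0 were used. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a probe set, so a shift shared by all genes of an array cannot be seen in such values. The array's annotation version and the genome build are not given in the sources used here, and no coordinates are printed.

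The value table holds 41345 probe sets. The platform's gene table lists 25335 of them, 23521 with 1 gene symbol and 1814 with several, and the other 16010 are unnamed here. Of the probe sets with 1 gene, 23328 were matched by Entrez number to a RefSeq gene table of the GRCm38.p6 assembly, used for names only. Values of the 1082 genes with more than 1 probe set were averaged on the log2 scale, which left 22180 genes. Probe sets with several genes or none stayed out of the counts and lists. Genes of large families with similar sequences, such as the Ifi204, Ifi205 and Ifi209 group, the Cyp2a, Cyp2b, Cyp2c and Cyp4a enzymes and Usp17ld, can share probes and their values are uncertain.

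A background level was set from 1105 olfactory receptor genes, taken as silent in hepatocytes: the 95th percentile of their mean was 4.764 (log2). A gene counted as detected in a comparison when it was above this level on at least 1 of the arrays compared. Where the dimmer array lay below the background, a fold is given as "at least", against the background level.

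Differences of log2 values were taken for 5 comparisons: fructose minus control in WT and in KO, KO minus WT in control and in fructose medium, and the fructose effect in KO minus that in WT. With 1 array per group there is no spread between replicates, so no p-value, standard error or test is given, and genes were counted by size alone, at 2-fold. No paired test was made. The control and fructose arrays of a genotype are already compared directly, and pooling both genotypes would use the difference of effects under study as its error. With 1 array per group no array could be left out, and the number of arrays limits the precision of every value.

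Before the data were examined, 38 gene lists with 780 members were fixed from textbook knowledge, covering carbohydrate and lipid metabolism, stress, inflammation, hepatocyte function and markers of other liver cells. Of the members, 691 had a value, 35 had only probe sets with several genes and 54 were not analysed here. Each list with at least 5 detected members was described by the median log2 difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is called outside the random range at or under percentile 2.5 or at or above 97.5. The percentile describes these arrays and is not a p-value. Lists share members: 10 of the 17 measured lipogenesis genes are also in the ChREBP target list. A further 3 lists (hypertonicity, hypoxia and YAP targets) were written after the data were seen.

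Named genes were chosen by a rule fixed before the data were examined. Mlxipl comes first. For each comparison the rule takes the 12 genes with the largest difference in each direction, leaving out predicted genes, small RNAs and olfactory or vomeronasal receptors, then 4 members of each list outside the random range. It adds the 4 members with the largest difference in any comparison from the ChREBP, lipogenesis, fructolysis and hepatocyte lists. Other members of the fixed lists are named where a list is described, and these were chosen after their values were seen.

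Alternatives fixed before the data were examined were median centring, repeated quantile normalization, a loess correction with span 0.3, no filter on dim genes, a stricter filter 1 log2 unit above background, thresholds of 1.5-fold and 3-fold, the brightest probe set per gene, unmatched random lists, the mean in place of the median, and each list without its most different member. Raising values to the background level was added after the data were seen.

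The list percentile and the counts were tested on simulated data built from the real values. Of 1000 simulated lists of 20 genes without a shift, 5% fell outside the random range for fructose in WT (10814 genes), 3.7% for fructose in KO (10752 genes), 4.3% for KO against WT in control medium (10720 genes), 5.2% in fructose medium (10688 genes) and 3.9% for the difference of effects (11050 genes). A shift of 0.4 was recovered in 89% of 200 lists for fructose in WT and 96.5% for fructose in KO, and a shift of 0.2 in 40% and 54%. Of 200 genes shifted by 1, 68.5% were counted at 2-fold for fructose in WT. The shifts given to earlier lists stayed in the simulated values, so later lists and these 200 genes came from values already partly raised. The recovery rates with a shift are therefore not exact, and the 68.5% is too high. Simulated members were drawn at random from shuffled values, so a rate near 5% without a shift follows from the construction. Members of real lists can vary together, so the simulation does not give how often a real list falls outside by chance. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.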

Results

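The data were log2 expression values of 22180 named genes on 4 arrays, 1 each for WT control, WT fructose, KO control and KO fructose hepatocytes. ChREBP is a transcription factor that activates glycolytic and lipogenic genes when sugars are abundant, and the design asks how its absence alters the fructose response. Between 10368 and 10447 genes lay above the background level on each array. Over 11050 genes, the correlation across genes was 0.992 between the control arrays of both genotypes, 0.982 between their fructose arrays, 0.947 between WT control and WT fructose and 0.968 between KO control and KO fructose. No difference below has a replicate check.

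Mlxipl, the targeted gene, had log2 levels of 8.08 in WT control, 8.43 in WT fructose, 7.42 in KO control and 7.37 in KO fructose. It was 1.58-fold lower in KO in control medium and 2.09-fold lower in fructose medium, and stayed well above the background of 4.764 on both KO arrays. The labels do not say which part of the gene was deleted, and the probe set may lie outside it, so this value is a limited check of the genotype.

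In WT hepatocytes, fructose was accompanied by higher levels of ChREBP targets and lipogenic genes. Fgf21, a liver-secreted metabolic hormone, was higher by a log2 difference of 4.32 and Klf10, a zinc-finger transcription factor, by 3.33. Txnip, an inhibitor of thioredoxin, was 14.7-fold higher and G6pc, the catalytic subunit of glucose-6-phosphatase, 12.1-fold. Of 23 detected ChREBP targets, 11 were at least 2-fold higher and 1, Gpam, was 2-fold lower (log2 difference -1.11), with a median of 0.84 (percentile 100). Pklr, the liver pyruvate kinase and a known ChREBP target, was not higher (-0.32). Among lipogenic genes, Acaca was higher by a log2 difference of 1.82, Acly by 1.81, Fasn by 1.76 and Mid1ip1 by 1.06, while Scd1 differed by -0.03. The lipogenesis list had a median of 0.77 (percentile 100), with 5 of 16 members 2-fold higher and 0 lower.

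Some genes of fructose and glucose metabolism were also higher in WT. Tkfc, which phosphorylates glyceraldehyde in fructolysis, was 2.42-fold higher, Gckr 2.11-fold, Slc2a2, the hepatic glucose and fructose transporter, 2.05-fold, and Khk, ketohexokinase, 1.74-fold, whereas Mpi was 2.44-fold lower. The fructolysis list had a median of 0.38 (percentile 98.1, 9 members), which was no longer outside the random range with the mean (0.24) or without the dim filter (0.17). Gluconeogenesis genes had a median of 0.92 (percentile 100), with 4 of 11 at least 2-fold higher, including Tat (4.65-fold), Got1 (2.06-fold) and Mdh1 (2.04-fold). Gys2, liver glycogen synthase, was 4.63-fold higher and Ugp2 1.71-fold. The glycogen metabolism list had a median of 0.44 (percentile 99.7, or 0.25 and percentile 94.8 with the mean). Of its 11 members, 1 was at least 2-fold higher and 1 lower, and at 1.5-fold 3 were higher and 3 lower. Amino acid catabolism and urea cycle genes had a median of 0.57 (percentile 100), with Haao 3.11-fold, Agxt 2.96-fold and Cps1 2.65-fold higher.

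Endoplasmic reticulum (ER) chaperones made up the list with the largest median in WT, 1.65 (percentile 100), with 14 of 18 members at least 2-fold higher and all 18 above 0. Sdf2l1 was 16.4-fold higher, Creld2 8.79-fold, Hyou1 6.19-fold and Dnajb9 6.02-fold. Derl3, a component of ER-associated degradation, was at least 50.3-fold higher, the largest difference of any named gene. The integrated stress response list had a median of 0.69 (percentile 100), with Ddit3 (CHOP) 9.14-fold, Atf3 7.20-fold, Chac1 4.62-fold and Ppp1r15a 4.33-fold higher. Immediate early genes had a median of 0.64 (percentile 100), with Zfp36 3.21-fold and Jun 1.98-fold higher, and Klf4 at least 1.87-fold. Heat shock genes (0.18, percentile 89.5), NRF2 targets (0.07, percentile 86.0) and p53 targets (-0.10, percentile 24.9) lay inside the random range.

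Inflammatory genes in WT included Nos2, inducible nitric oxide synthase, 13.6-fold higher with fructose, Cxcl2 4.59-fold, Ccl3 3.35-fold and Ccl5 2.77-fold, with a list median of 0.24 (percentile 99.0), and Il23a was at least 20.7-fold higher. This list's median lay inside the random range with the stricter filter, with values raised to the background and without Nos2 (percentiles 96.5, 96.2 and 96.8). Macrophage markers had a median of 0.20 (percentile 96.2) and endothelial markers -0.13 (percentile 19.9). Interferon-response genes were lower, with a median of -0.34 (percentile 0.24): Oasl2 was 2.99-fold lower, Ifih1 2.11-fold, Oas2 1.89-fold and Irf7 1.83-fold. Clock genes had a median of 0.49 (percentile 100), with Nfil3 3.90-fold, Bhlhe41 2.77-fold and Per1 2.70-fold higher. Bile acid genes had a median of 0.33 (percentile 99.8), with Slco1b2 higher by 1.81 (log2), Abcb11, the bile salt export pump, 2.49-fold and Slc10a1 2.19-fold. Cytochrome P450 and phase II genes had a median of 0.20 (percentile 98.4), inside the range under 3 alternatives (percentiles 93.7 to 96.5). Their differences were mixed. Of 20 members, 3 were at least 2-fold higher, Cyp2b10 (8.04-fold), Sult1a1 (2.46-fold) and Sult2a8 (2.27-fold), and 2 were lower. At 1.5-fold, 4 were higher and 4 lower.

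Other genes with large differences in WT were Cyp4f15 (10.9-fold higher), Slc25a47 (10.4-fold), Prss8 (9.34-fold) and Aloxe3 (9.25-fold). The lowest were Cdh17, an intestinal-type cadherin, at least 9.70-fold lower, Osbpl3 at least 10.5-fold, Ifi27l2b 9.66-fold, Ankrd23 9.63-fold, Spon2 6.20-fold, Smpd3 5.78-fold, Slc4a11 and Vnn3 4.64-fold each, Tmem71 4.57-fold, Hjv, the hemojuvelin gene, 4.47-fold, Fblim1 4.41-fold and Pllp at least 3.94-fold. Hepatocyte identity genes had a median of 0.01 (percentile 71.0), within which Foxa1 was 2.22-fold higher, and Hnf4a was 1.68-fold and Prox1 1.84-fold lower. Control genes had a median of -0.04. Cholangiocyte markers had a median of -0.47 (percentile 1.94) over 5 members, among them Cldn3 at -0.90 and Sox9 at 0.47, and this value turned to 0.02 without the dim filter. In all, 335 genes were at least 2-fold higher and 326 lower among 10814 detected in WT.

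**Figure D1:**
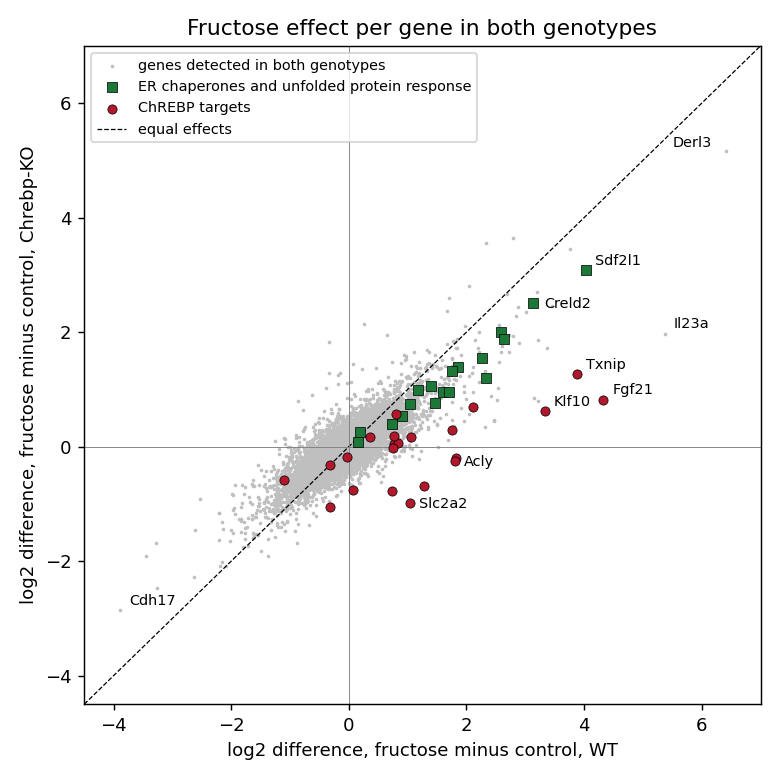
Each point is 1 gene detected in both genotypes, with the log2 difference between fructose and control medium in WT on the horizontal axis and in KO on the vertical axis, and the dashed line marks equal effects. ER chaperone genes (green squares) lie above 0 on both axes, with medians of 1.65 in WT and 1.03 in KO, while ChREBP targets (red circles) have medians of 0.84 and 0.01.

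In KO hepatocytes, the ER and stress genes were again higher with fructose, whereas ChREBP targets as a group were not. Derl3 was at least 21.1-fold higher, Sdf2l1 8.48-fold, Creld2 5.71-fold, Hyou1 3.66-fold and Dnajb9 by a log2 difference of 2.00, and the ER list had a median of 1.03 (percentile 100), with 9 of 18 members at least 2-fold higher. Nupr1 was 7.03-fold, Ddit3 6.48-fold, Atf3 4.88-fold and Ppp1r15a 2.62-fold higher, with a median of 0.59 for the integrated stress response (percentile 100). The ChREBP target median was 0.01 (percentile 53.3), with 1 of 22 members 2-fold higher, Txnip (2.40-fold), and 1 lower, Pklr (-1.05). Fgf21 was 1.76-fold higher, Klf10 1.54-fold and Fasn 1.22-fold, Acly was 1.19-fold and Acaca 1.15-fold lower, and G6pc was below background on both KO arrays. The lipogenesis list had a median of 0.07 (percentile 74.7), with 0 of 16 members at 2-fold.

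The fructolysis list had a median of -0.49 in KO (percentile 0.05), with Slc2a2 1.97-fold, Tkfc 1.61-fold, Glyctk 1.57-fold and Mpi 1.47-fold lower, and this was inside the random range with the mean (percentile 7.14) or without Slc2a2 (percentile 3.53). Fatty acid oxidation genes had a median of -0.31 (percentile 0.01), with Aldh3a2 2.27-fold, Vnn1 2.25-fold, Cpt1a, the mitochondrial entry step for long-chain fatty acids, 2.16-fold and Bdh1 1.92-fold lower. The same list had a median of -0.19 in WT (percentile 7.13), where Vnn1 was 3.84-fold, Cpt1a 2.72-fold and Bdh1 1.62-fold lower. Members went both ways. In WT, 3 of 22, Fgf21 among them, were at least 2-fold higher and 2 lower, and in KO 1 of 21 was higher and 3 lower. Gluconeogenesis genes had a median of 0.59 (percentile 100), with Tat 4.02-fold, Pck1 3.05-fold, Mdh1 1.86-fold and Pck2 1.71-fold higher. Amino acid and urea cycle genes had a median of 0.33 (percentile 100), with Haao 2.67-fold, Cps1 2.63-fold and Agxt 2.33-fold higher.

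Immediate early genes had a median of 0.40 in KO, with Zfp36 2.13-fold, Dusp1 1.93-fold and Fos 1.88-fold higher, and clock genes 0.31, with Per1 2.73-fold and Nfil3 2.08-fold higher. Inflammatory genes had a median of 0.25 (percentile 99.1; 96.3 without Nos2), with Nos2 at least 8.45-fold, Ccl5 3.03-fold and Ccl3 2.93-fold higher, while macrophage markers had a median of 0.01 and endothelial markers -0.03. Interferon genes had a median of -0.26 (percentile 0.06), with Oasl2 2.24-fold and Irf7 2.01-fold lower. Cell cycle genes had a median of 0.30 (percentile 99.5, 10 members), with Mcm6 2.00-fold and Pcna 1.40-fold higher, and a median of 0.23 (percentile 95.8) in WT, and the KO value was inside the range under 3 alternatives (percentiles 83.6 to 96.8). Among the largest single differences were Il1f9 (12.6-fold higher), Muc13 (11.8-fold), Adm, the adrenomedullin gene (6.37-fold), Cyp4f15 (at least 5.29-fold), Car2 (5.15-fold) and E2f8 (at least 2.98-fold). The lowest were Cdh17 (7.27-fold lower), Ankrd23 (5.54-fold), Spon2 (4.84-fold), Vil1 (4.24-fold), Tmem71 (4.22-fold), Hjv (4.06-fold) and Osbpl3 (3.75-fold).

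In KO, 181 genes were at least 2-fold higher and 127 lower among 10752 detected. Over the 10516 genes detected in both genotypes, 138 were higher in both, of 323 in WT and 180 in KO, where independent lists of these sizes would share 5.53, and 107 were lower in both, of 320 and 126, against 3.83. The comparisons use separate arrays. Of the 323 genes higher in WT, 313 had a difference above 0 in KO. The correlation of the 2 fructose effects across genes was 0.83 (Spearman 0.79), and genes are not independent replicates.

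**Figure D2:**
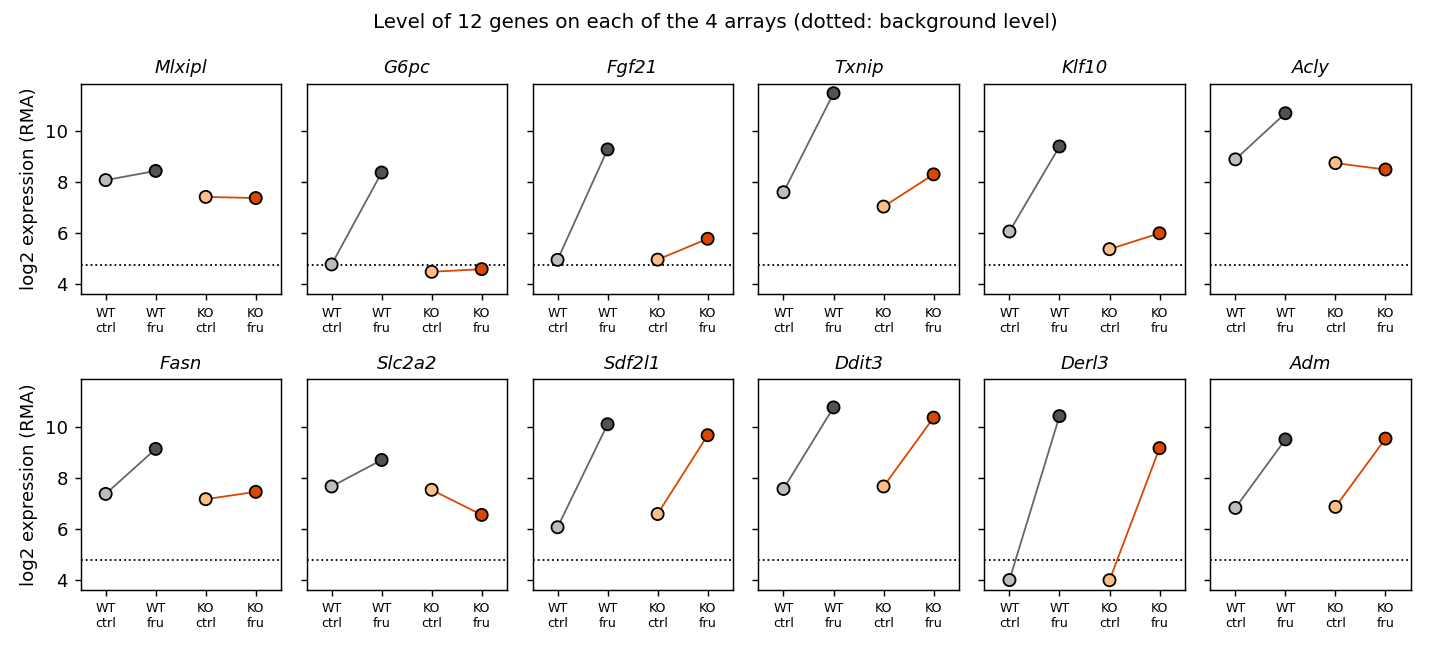
The log2 expression of 12 genes is shown on the 4 arrays, 1 point per array, with lines joining control and fructose within a genotype and a dotted line at the background level of 4.764. Fgf21 reached 9.28 in WT fructose and 5.78 in KO fructose, whereas Adm reached 9.50 and 9.53.

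In control medium, the genotypes differed little, and the lower genes in KO included interferon-inducible and macrophage genes. Cd274, the gene of PD-L1, was 2.44-fold lower in KO, Cxcl11 2.31-fold, Cxcl10 2.20-fold, Tnfsf10 2.16-fold and Ifit2 2.09-fold. Fcgr1, a macrophage Fc receptor gene, was 2.38-fold lower, Igsf6 2.36-fold, Acod1 2.35-fold and Cd180 at least 2.24-fold. Ifi204 was 2.45-fold, Ifi205 2.20-fold, Ifi209 at least 1.77-fold and Apela at least 1.63-fold lower. The interferon list had a median of -0.38 (percentile 0), with 2 of 23 members 2-fold lower and all 23 below 0, and the inflammatory list -0.38 (percentile 0), with Tnf 1.62-fold and Ccl3 1.56-fold lower and Nos2 at least 1.32-fold. Macrophage markers had a median of -0.38 (percentile 0, 14 members), with C1qb 1.94-fold, Timd4 1.75-fold and Marco 1.65-fold lower, although Csf1r differed by -0.05 and Cd68 by 0.08. Endothelial markers had a median of -0.32 (percentile 0), all 14 below 0, with Cdh5 1.60-fold and Dnase1l3 1.56-fold lower, while hepatocyte identity genes had a median of 0.00 (percentile 57.2).

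ChREBP targets were lower in KO control cells by a small amount, with a median of -0.21 (percentile 0) and 0 of 23 members at 2-fold: Klf10 was 1.62-fold, Pklr 1.59-fold, Me1 1.55-fold and Khk 1.52-fold lower. Lipogenesis genes had a median of -0.16 (percentile 0.04), with Thrsp 1.49-fold and Elovl6 1.29-fold lower. Acute phase genes had a median of -0.12 (percentile 0.01), with Hamp, the hepcidin gene, 1.44-fold and Lbp 1.37-fold lower. Cytochrome P450 and phase II genes had a median of 0.13 (percentile 100), with Cyp2b10 2.01-fold, Cyp2c37 1.67-fold, Sult1a1 1.60-fold and Cyp2a5 1.56-fold higher, and fatty acid oxidation genes 0.09 (percentile 99.5), with Cyp4a14 at least 1.96-fold, Acot2 1.43-fold and Acadm 1.34-fold higher. Fezf1 was 1.88-fold and Exph5 1.74-fold higher, and Cyp39a1 was higher by a log2 difference of at least 0.59. The medians of pentose phosphate genes (-0.13, percentile 2.36; Taldo1 -0.27) and oxidative phosphorylation genes (0.06, percentile 97.7; Cox7a2 0.38) were just outside the random range and inside it under several alternatives (percentiles up to 5.74 and down to 94.8). Only 4 genes were at least 2-fold higher and 21 lower among 10720 detected.

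In fructose medium, KO cells had lower levels of ChREBP targets, with a median of -1.41 (percentile 0), 15 of 23 members at least 2-fold lower and 1, Gpam, higher (1.08). G6pc was at least 12.2-fold lower in KO, Fgf21 11.3-fold, Klf10 10.5-fold, Txnip 9.05-fold, Acly 4.61-fold, Slc2a2 4.44-fold, Tkfc 4.24-fold, Acaca 3.98-fold, Fasn 3.21-fold and Me1 2.66-fold. Outside that list, Rgs16 was 10.2-fold lower, Il23a 8.49-fold, Prss8 7.68-fold, Angptl8, a secreted inhibitor of lipoprotein lipase, 4.71-fold and Ifi30 4.58-fold, and Slc25a47 differed by -2.26 (log2). The lipogenesis list had a median of -0.60 (percentile 0), with 7 of 16 members at least 2-fold lower. ER chaperone genes had a median of -0.41 (percentile 0), all 18 below 0, with Sel1l 2.10-fold, Dnajb11 1.86-fold, Herpud1 1.66-fold and Creld2 1.51-fold lower.

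Macrophage markers (-0.56, percentile 0), endothelial markers (-0.27, percentile 0.06), interferon genes (-0.26, percentile 0) and inflammatory genes (-0.23, percentile 0.06; 8.16 with values raised to the background) were again lower in KO, with Fcgr1 2.05-fold, Timd4 2.02-fold, Dnase1l3 1.84-fold, Ifit2 2.09-fold, Cxcl10 1.71-fold, Cxcl2 2.14-fold and Nos2 2.12-fold lower. Cd68 was higher (0.44). The medians of the integrated stress response (-0.11; Chac1 2.58-fold lower), immediate early (-0.12; Zfp36 1.87-fold, Egr1 1.84-fold lower), clock (-0.13; Nfil3 1.49-fold lower) and bile acid (-0.12; Baat at least 1.33-fold lower) lists were outside the random range (percentiles 1.33 to 2.19), and inside it under 2 to 5 alternatives each. Higher in KO were Cldn4 (3.91-fold) and Cldn1 (3.54-fold), which encode tight junction claudins, Foxn1 (at least 4.57-fold), Ivl (3.74-fold), Avpr1a, a vasopressin receptor gene (3.32-fold), Osbpl3 (at least 3.18-fold), Exph5 (3.14-fold), Kitl (2.98-fold), Ankrd1 (2.75-fold) and Cyp4a14 (2.72-fold). Genes of cultured hepatocyte dedifferentiation had a median of 0.23 (percentile 100), with Vim 2.14-fold, Anxa3 2.14-fold and Ccn2 1.84-fold higher and S100a6 at least 1.70-fold, and this lay inside the random range without the dim filter (0.04, percentile 75.1). Cytochrome P450 genes had a median of 0.17 (percentile 99.8), with Cyp2a5 2.70-fold and Cyp3a13 1.68-fold higher. In all, 58 genes were at least 2-fold higher and 79 lower among 10688 detected. Among the 10358 genes detected in both media, 9 of the 20 genes lower in control medium were also among the 70 lower here, against 0.135 for independent lists. A difference between the KO and WT cell preparations could recur in both media, so this overlap is not a replicate of a genotype effect.

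**Figure D3:**
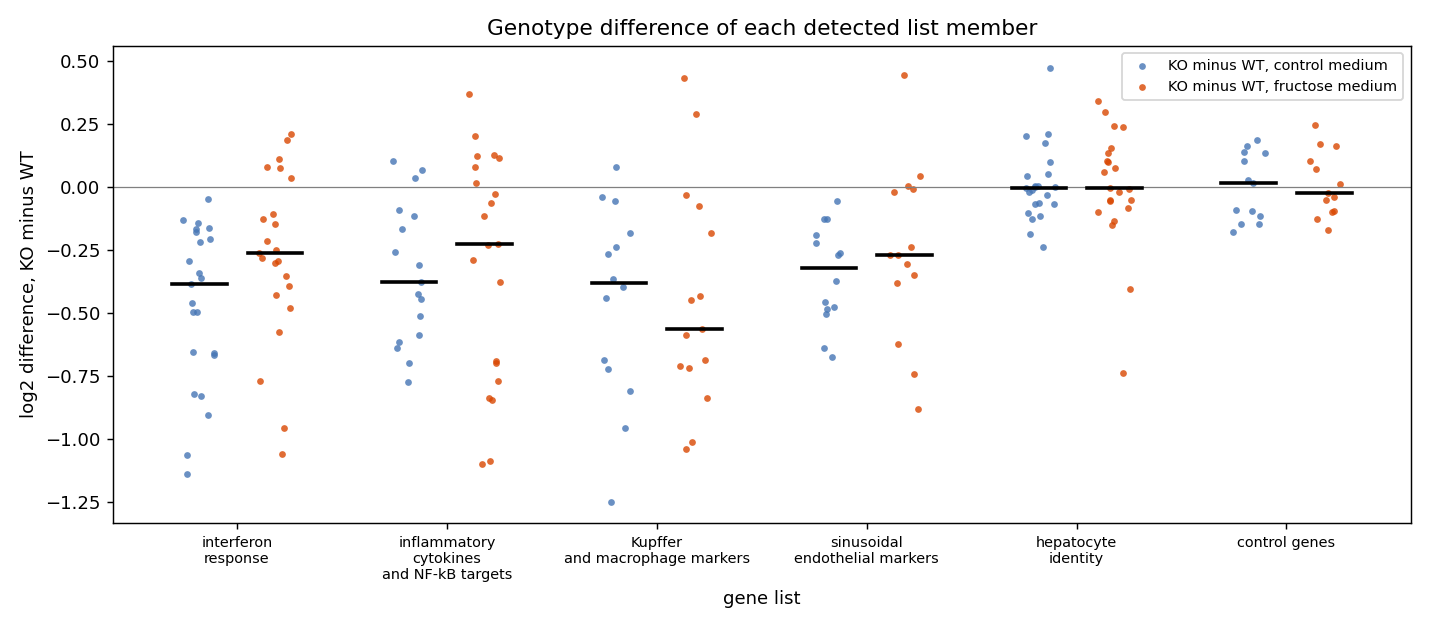
Each point is 1 detected member of a gene list, with the log2 difference between KO and WT on the vertical axis, in control medium (blue) and in fructose medium (orange), and black bars mark medians. Interferon, inflammatory, macrophage and endothelial lists have medians between -0.56 and -0.23, and hepatocyte identity and control genes lie near 0.

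The fructose effect in KO minus that in WT was lowest for Fgf21 (log2 -3.51), G6pc (-3.49), Il23a (-3.40), Klf10 (-2.71), Txnip (-2.62), Prss8 (-2.42), Rgs16 (-2.29), Acly (-2.06), Fam171b (-2.03), Acaca (-2.02), Slc2a2 (-2.02) and Ifi30 (-2.01). G6pc, Il23a and Fam171b were below background on 2 of the 4 arrays, so their differences are inexact. ChREBP targets had a median of -0.89 (percentile 0), with 11 of 23 members at -1 or lower, and lipogenesis genes -0.60 (percentile 0), with Fasn at -1.47 and Mid1ip1 at -0.89. ER chaperones had a median of -0.53 (percentile 0), with Sel1l at -1.14, Sdf2l1 at -0.95 and Hyou1 at -0.76. The hepatokine list had a median of -0.15 (percentile 0.18), with Angptl8 at -1.71, Inhbe at -0.72 and Igfbp1 at -0.56. Smaller negative medians were found for the integrated stress response (-0.17, Chac1 -1.08), gluconeogenesis (-0.13, Slc37a4 -0.76), immediate early (-0.12, Zfp36 -0.60) and amino acid (-0.12, Glul -0.95) lists. Of these, gluconeogenesis was inside the random range under 3 alternatives (percentiles 3.92 to 7.35). Their median ratios of the KO to the WT effect were 0.80, 0.89, 0.70 and 0.82, against 0.79 for changed genes in no list. The gluconeogenesis ratio covers 10 genes and leaves out G6pc, which was below background on both KO arrays. Random lists were matched on expression and not on the fructose effect, so these negative medians need not be particular to the lists.

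Positive differences of effects were found for Foxn1 (2.16), Krtap4-16 (1.90), Cldn4 (1.66), Duox2 (1.64), Smpd3 (1.62), Ifi27l2b (1.59), Osbpl3 (1.54), Ivl (1.52), Kitl (1.43), Itga2 (1.43) and Ntn4 (1.41), with Foxn1 and Osbpl3 below background on 1 array. Interferon genes had a median of 0.20 (percentile 99.8), with Ifih1 at 0.48 and Oas2 at 0.44, beside medians of -0.12 for macrophage and 0.02 for endothelial markers. The interferon list was lower with fructose in both genotypes, with medians of -0.34 in WT and -0.26 in KO. Dedifferentiation genes also had a median of 0.20 (percentile 99.8), with Vim at 0.82 and Anxa3 at 0.78. In all, 49 genes had a difference of at least 1 and 65 of -1 or lower among 11050 detected. The difference itself was not tested against replicates.

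**Figure D4:**
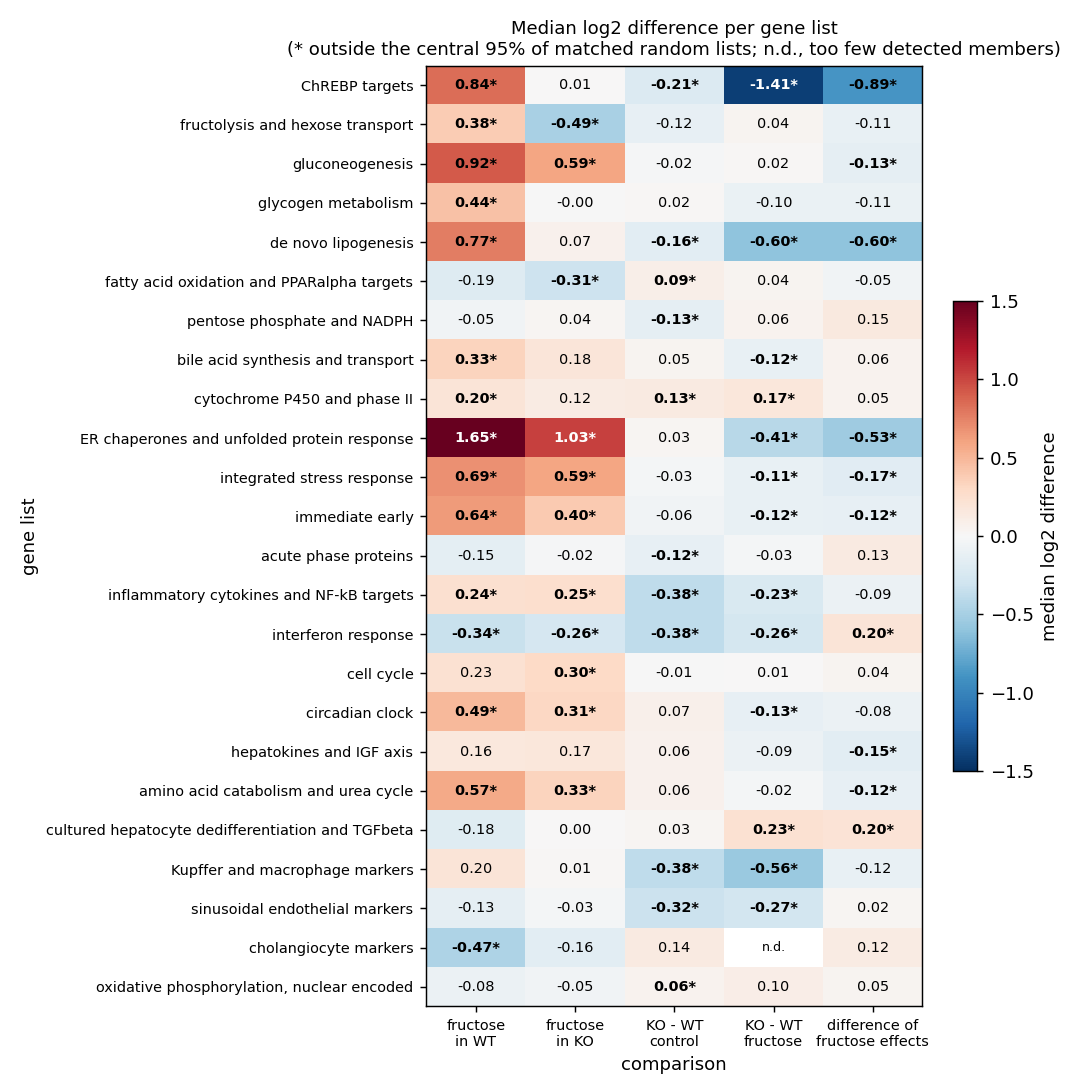
Median log2 differences of the gene lists outside the random range in at least 1 comparison are shown by list (vertical) and comparison (horizontal), with red for higher and blue for lower. Asterisks mark medians outside the central 95% of matched random lists, and the ChREBP target row runs from 0.84 for fructose in WT to -1.41 for KO against WT in fructose medium.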

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

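The tests of cell number, of the spread of macrophage markers and of interferon signalling were chosen only after the result was seen, as was the second reference for the ER genes.

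Among genes chosen by the naming rule with effects of at least 1.5-fold in both genotypes, 5 had opposite directions, and these differences were not tested against replicates. The effect in KO minus that in WT was 1.66 for Cldn4 (-0.87 in WT, 0.79 in KO), 1.43 for Itga2 (-0.78 and 0.65), 1.52 for Ivl (-0.62 and 0.90), -2.02 for Slc2a2 (1.04 and -0.98) and -1.96 for Tkfc (1.28 and -0.68). The fructolysis list had a median of 0.38 in WT and -0.49 in KO, but the difference of effects over its 9 members had a median of -0.11, inside the random range (percentile 6.56), and with the mean both effects were inside it too (percentiles 91.4 and 7.14). Probe sets left out of the comparisons also showed differences with fructose. Of 832 detected with several genes, 20 were at least 2-fold higher and 21 lower in WT, and of 822 in KO, 9 and 6. Without a listed gene, 132 were higher and 122 lower of 4663 in WT, and 86 and 71 of 4659 in KO. These last also gave 51 higher and 45 lower of 4634 for KO against WT in control medium, against 4 and 21 of 10720 named genes.

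Macrophage, endothelial and interferon genes were lower in KO in both media. Rescaling decides nothing about the cause, since the values had been normalized before deposit and 3 rescalings moved the median of all genes in control medium by at most 0.0153 (interferon median -0.37 or lower). Fewer macrophages and endothelial cells in the KO samples may account for it, as all 4 medians of their markers were below 0, the highest at -0.27. Whether other non-parenchymal cells were fewer cannot be told, as few of their markers were detected. Stellate markers had a median of 0.13 in fructose medium and cholangiocyte markers 0.14 in control medium (5 members each), both inside the random range (percentiles 85.4 and 97.2). With 4 members each in the other medium, they ranged from -0.50 to 0.25 and from -0.09 to 0.61. Lymphocyte markers ranged from -0.26 to 0.06 in control medium (4 members) and from -0.53 to 0.02 in fructose medium (3 members). Macrophage number as the only cause, a test added after the one before, stayed open: the members differed among themselves more than matched random lists in control medium (percentile 99.7 of the SD) but not beyond the random range in fructose medium (93.8). Lower interferon signalling in the KO hepatocytes themselves (interferon median -0.38) cannot be told apart from a difference in cell composition, because each group is 1 array and the marker medians were lower too.

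ChREBP targets had a median fructose effect of 0.01 in KO, against 0.84 in WT, with members going both ways. Of the 22 detected in KO, 4 were at least 1.5-fold higher and 6 at least 1.5-fold lower. A smaller fructose response of all genes in KO is argued against as the whole cause: the median ratio of the KO to the WT effect was 0.18 for ChREBP targets (95% bootstrap interval over genes -0.02 to 0.33) and 0.79 for 322 genes in no list with a mean effect of at least 2-fold. The interval covers the spread between genes, not between arrays. The genes in no list were chosen by their mean effect, which favours genes that kept an effect in KO. Immediate early (0.70) and integrated stress response genes (0.80) had ratios above this interval. Both lists were already outside the random range with fructose in KO, which makes a lost effect unlikely. Glycogen metabolism genes were given no ratio, and their median was 0.44 in WT and -0.002 in KO. Of 323 genes detected in both genotypes and at least 2-fold higher in WT, 244 were at least 1.5-fold higher in KO. This set was chosen by the WT effect alone. The absence of ChREBP remains a hypothesis for the lost effect on ChREBP targets, and a difference between cell preparations was not tested.

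ER chaperone genes had a smaller fructose effect in KO. By the bound set before the values were seen, the ER ratio lay below that of other changed genes: the median was 0.71 (0.58 to 0.76) against 0.79. Those reference genes were chosen by their mean effect, which favours genes that kept an effect in KO, and the ER genes were not. The test therefore cannot decide whether a smaller response of all genes is the whole cause. Against the 155 genes that were higher alone, a reference added later and chosen the same way, the gap was 0.07 (-0.02 to 0.23). The result thus also rests on the choice of reference. Rescaling decides nothing here either, since it moved the median of all genes by 0.0379 at most (ER median -0.55 or lower). Fructose metabolism was not measured on these arrays, and whether a difference in it contributes to the smaller effect was not tested.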

How the results depend on the processing

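Raising values to the background was chosen only after the data were seen. Counts kept within 1.5 times of their main value under every rescaling, the brightest probe set and no dim filter, and moved with the size threshold by its construction. At 1.5-fold, genes higher and lower were 1023 and 1172 for fructose in WT, 657 and 618 in KO, 51 and 118 for KO against WT in control medium, 262 and 306 in fructose medium, and 316 and 287 for the difference of effects; at 3-fold they were 103 and 57, 47 and 18, 0 and 2, 8 and 21, and 6 and 16. The 4 genes higher in KO control cells became 1 with the stricter filter and 1 with values raised to the background, since dim genes are removed or reduced. The cholangiocyte median for fructose in WT (5 members) reversed to 0.0214 without the dim filter, which adds members at background. Of 60 list medians outside the random range, 43 stayed outside under every alternative; the 4 ChREBP medians outside stayed outside, and that for fructose in KO stayed inside with values of either sign (-0.04 with the mean). No rescaling moved the median of all genes by more than 0.04. Among named genes, 8 dropped under 2-fold with values raised to the background, among them Cyp4a14 (0.97), Ifi209 (-0.82) and Apela (-0.70), and Vim did with the brightest probe set (0.92). Signal near background limits what these arrays can show: G6pc in KO and Derl3 in control medium have only bounds. No paired test was made, because its error would be the difference of effects under study, and with 1 array per group no array could be left out.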

Other observations

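The tests of hypoxia and YAP targets were chosen only after the result was seen; the bound for the hypertonicity genes was set before its values were seen, was loosened after they were seen, and was then restored. Genes named in this part were chosen after their values were seen.

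Lipid droplet and sterol genes showed mixed differences with fructose. Cidec, a lipid droplet protein gene, was higher by 2.72 (log2) in WT and 1.96 in KO, and Fabp4 by 1.98 and 0.83, while Cd36, a fatty acid transporter gene, was lower (-1.17 and -0.97), as was Plin2 (-0.64 and -0.52). Mttp, needed for lipoprotein assembly, differed by 0.73 in WT and -0.78 in KO. The whole triglyceride list had medians of -0.13 in WT (percentile 16.1) and -0.09 in KO (percentile 12.1). In cholesterol synthesis, Insig1 was higher in both (1.35 and 1.18) and Mvd in WT (1.04, and -0.03 in KO), with list medians of 0.17 (percentile 94.7) and 0.07 (percentile 76.9).

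Other lists stayed inside the random range with fructose in WT: glycolysis (0.07, percentile 80.5; Pfkfb3 1.91), ribosomal proteins (-0.21, percentile 3.65), extracellular matrix (-0.21, percentile 12.7) and stellate cell markers (-0.02, percentile 47.7). Of lymphocyte markers 4 were detected there, with differences from -0.15 to 0.37, and 0 neutrophil and 0 erythroid markers.

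Adm and Egln3 were higher by the same amount in both genotypes (2.68 and 2.67; 1.85 and 1.87), which may reflect a response of the HIF type. Without these 2 genes, the other hypoxia targets had medians of 0.38 in WT (percentile 99.7, or 99.9 with them) and 0.56 in KO (percentile 100), with Pfkfb3 (1.91 and 1.60), Vegfa (1.54 and 1.35) and Ero1a (1.44 and 1.05) highest. Vegfa and Ero1a are also induced in ER stress, whose genes were higher as well, Ldha differed by only 0.07 and 0.15, and the bootstrap interval of the WT median over genes (0.07 to 0.44) reaches below the random bound of 0.24, so a HIF response is 1 of the open explanations.

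A response to the added osmolarity of 25 mM fructose could contribute to the stress genes, as the labels name no other sugar in the control medium. The hypertonicity list missed the upper bound of the random range in both genotypes, at percentile 97.4 in WT (median 0.41) and 88.2 in KO (median 0.20). The miss in KO was smaller than the spread between its 7 detected members (bootstrap interval of the median -0.09 to 0.42, against 0.34 at the bound), and 2 of its 10 fixed genes were not analysed here, so the test leaves this open.

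Ankrd1 was higher in KO than WT with fructose (2.75-fold), which may reflect a YAP-type response. YAP targets had a median of 0.23 (percentile 99.8, 14 members), with F3 at 1.07, Crim1 at 1.06 and Ccn2 at 0.88, and Ccn2 is also in the dedifferentiation list. The bootstrap interval of this median over genes (0.01 to 0.32) reaches below the random bound of 0.15, so the spread between members leaves this explanation weak. With fructose, the list had a median of -0.28 in WT (percentile 1.37) and 0.00 in KO (percentile 54.0).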
